A study of Homo sapiens with 9 samples.

How the data were processed

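Total RNA from 9 samples of HEK293 cells was labelled with biotin and measured on 9 oligonucleotide arrays, per the labels' protocols, 3 arrays for each of the wild type, overexpression and knockdown groups. The deposited values are the authors' linear intensity signals, 1 per probe set, made with MAS5, per the submitters' processing notes. Its version and parameters are not given in the sources used here. In the deposited table every array had the same 2% trimmed mean signal of 1500.2, which is what global scaling leaves, so a change in total RNA per cell cannot be seen in these values. MAS5 estimates each array by itself, and its signals of dim probe sets vary more between arrays. The array image files and the detection calls were not used here. The labels describe wild type cells as untreated, and the design text also mentions samples treated with an unrelated double-stranded RNA as control. No such samples are among the 9, so each comparison with wild type holds the transfection as well as the change in MOF. Samples were grouped by their titles.

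The deposited intensity was transformed to log2(signal + 1). After 62 control probe sets were left out, the 27307 probe sets whose mean log2 signal over the 9 arrays reached the median of all probe sets (7.564, a signal of about 188) were tested. Fold changes are on the log2(signal + 1) scale. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), in 1 fit over all 9 arrays with 6 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. Single values were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9.

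Probe sets were named from the platform's annotation table. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 several and 11777 none, and only those with 1 symbol were named. Of these, 41043 matched a gene by Entrez ID in a RefSeq table of the assembly GRCh38.p14, used for names alone, and no symbol needed an update. Where a gene had several tested probe sets, that of the highest mean signal stood for it. The genes named were set by a rule: KAT8, the 8 largest rises and 8 largest falls past the threshold in each comparison whose 3 arrays of one group lay above the 3 of the other and whose higher group reached the 75th percentile of signal, and up to 4 members of smallest p of each gene list. Some genes that met the rule were left out of the prose. Members of a list named beyond these, such as those that went against their list, were chosen after their values were seen.

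For the gene lists, 31 lists were fixed before the data were examined, as were the tests of the 3 comparisons, the rule for named genes and the other settings tried, save those named below as added after seeing the data. Of these, 30 had at least 4 measured members and were tested with limma's camera with a preset correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists. The list of blood cell markers had too few measured members. After overexpression 8 lists passed, and 3 held with an estimated correlation (immediate early, cholesterol synthesis, and unfolded protein and ATF4 stress). After knockdown 8 passed and 4 held (p53 targets, HOX, G2/M and mitosis, hypoxia and glycolysis). Between knockdown and overexpression 7 passed and 4 held (HOX, p53 targets, G2/M and mitosis, heat shock). With the term for replicate 1 and an estimated correlation, the immediate early list after overexpression (adjusted p = 0.0651) and the heat shock list between the treated groups (adjusted p = 0.0605) missed the threshold, and the others named here kept it.

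The arrays were compared before averaging. No 2 arrays held identical values, and correlations of log2 signal within groups ran from 0.973 to 0.985. The added poly-A control transcripts were 2.23-fold brighter in the 6 arrays of replicates 2 and 3 than in the 3 replicate 1 arrays, with no overlap, and the hybridization controls 1.19-fold, so the replicate 1 arrays, 1 of each group, were treated as a possible batch. A term for it was fitted as an alternative, and calls within replicates 2 and 3 were set beside the signs in replicate 1. Whether replicate numbers pair the samples was checked from the labels' numbers by correlating deviations from the group means. Between arrays of the same number these ran from 0.35 to 0.45 for replicate 1, from 0.14 to 0.24 for replicate 2 and from 0.083 to 0.14 for replicate 3. Between arrays of replicates 2 and 3 with different numbers they ran from 0.029 to 0.28, so beyond replicate 1 arrays of the same number did not stand out. Still, every pair of knockdown with wild type or with overexpression was over 0.1, which was the bound for pairing, so those comparisons are given with the replicate number as a block as well. The pair of wild type and overexpression replicate 3 was at 0.083.

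The limma fit was tested on simulated log2 values, drawn independently for each probe set. In these, 80 probe sets were changed by 0.5, 80 by 1 and 40 by 2 on the log2 scale among 27307. The log2 transform and the filter were not part of the simulation. In the real data 4289 probe sets passed after knockdown, far more than were changed here, so the rates below may not hold there. With a simulated batch and no term for it, 11.2%, 67.5% and 95% of these were recovered for overexpression against wild type, and 7.5%, 60% and 92.5% for knockdown against wild type, all with the right sign and with 0 false calls. With the term 53.8%, 77.5% and 97.5% were recovered for overexpression against wild type, with 7.1% of the calls false. In simulations without a batch, 8.48% of calls were false for overexpression and 6.41% for knockdown. For shared wild type arrays, 100 simulations of unchanged groups were drawn from the fitted residual variances, and another 100 from those of the fit with the term for replicate 1.

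The alternatives tried were no filter, a filter at the 75th percentile, an offset of 16, quantile normalization, median centring, the replicate block, the term for replicate 1, no variance trend, array weights, only the 2 groups compared, each replicate left out in turn, a 2-fold threshold, the mean of each gene's probe sets, each gene's other probe sets, each control gene alone, camera with an estimated correlation, and fry. A fit of replicates 2 and 3 alone, and the simulations with the residual variances of the fit with the term for replicate 1, were added after seeing the data.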

Results

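RNA from HEK293 cells, an established human embryonic kidney line, was profiled on oligonucleotide expression arrays, with 1 array per sample. The 9 arrays fell into 3 groups of 3: untreated wild type cells, cells transfected with a plasmid encoding MOF, and cells in which MOF was depleted with small interfering RNA. MOF is the product of KAT8, a histone acetyltransferase that acetylates lysine 16 of histone H4. The title of the series ties altered MOF levels to the DNA damage response, so the comparisons ask which transcripts differed after MOF overexpression or knockdown, and whether genes of DNA damage signalling and repair were among them. Each array held 54675 probe sets, of which 27307 were tested after dim probe sets were left out, representing 12036 genes. The precision is limited by 3 arrays per group. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

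KAT8 was measured first, as a check of the labels. The brighter of its 2 tested probe sets had a mean signal of 3318 ± 448 (SD, n = 3) in wild type cells, 4695 ± 88.9 (SD, n = 3) after overexpression and 551.6 ± 140 (SD, n = 3) after knockdown. The knockdown samples held 16.4% of the wild type signal, a log2 fold change of -2.61 (SE 0.17, limma adjusted p = 4.72e-05), and all 3 knockdown arrays lay below all 3 wild type arrays. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 arrays allow. After overexpression the signal was 1.42 times that of wild type, log2 fold change 0.51 (SE 0.17), which did not pass the test (limma adjusted p = 0.259) although the 3 overexpression arrays lay above the 3 wild type arrays. With a term for the replicate 1 arrays, which stood apart as described with the processing, the adjusted p of that rise was 0.0478. The dimmer probe set fell after knockdown by 1.58 on the log2 scale (SE 0.26, limma adjusted p = 0.00296) and had a log2 fold change of 0.11 (SE 0.26, limma adjusted p = 0.91) after overexpression. A probe set outside the plasmid's insert would not read the plasmid's transcript, and where the insert ends is not given in the sources used here.

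**Figure D1:**
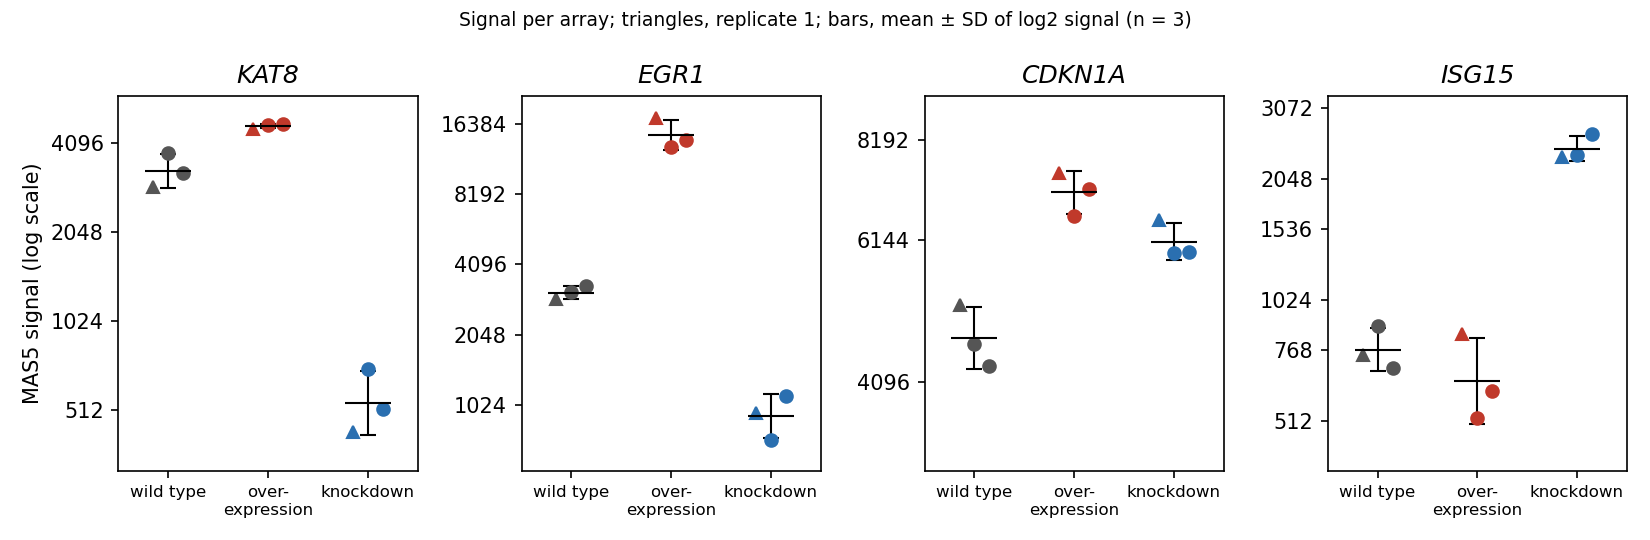
MAS5 signal on a log scale for KAT8, EGR1, CDKN1A and ISG15 in each of the 9 arrays, by group. Points are arrays, triangles mark replicate 1, and the black bars give the mean and SD of the log2 signal (n = 3). KAT8 lay at 551.6 after knockdown against 3318 in wild type, EGR1 was above wild type after overexpression and below it after knockdown, CDKN1A was above wild type in both treated groups, and ISG15 was above wild type after knockdown.

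Overexpression against wild type asked what changed in cells transfected with the MOF plasmid. Of 18 genes of the immediate early response, which cells switch on within minutes of growth factor or stress signals, 8 rose, and of 15 genes of cholesterol synthesis 3 fell. Both lists passed the limma camera test (adjusted p = 3.61e-15 and 6.71e-10), the immediate early list with adjusted p = 0.0651 with an estimated correlation and a term for the replicate 1 arrays. EGR1, a zinc finger transcription factor, rose 4.72-fold (log2 fold change 2.24, SE 0.16, n = 3 per group, limma adjusted p = 0.000226). MAFF, a small basic leucine zipper factor, rose 4.36-fold (log2 2.12, SE 0.12), CCN1, a secreted matrix protein, rose 3.14-fold (log2 1.65, SE 0.12) and the stress-induced factor ATF3 rose 2.36-fold (log2 1.24, SE 0.10). ZCCHC12 rose by 1.32 on the log2 scale (SE 0.13), and SYTL5, GEM and PPP1R15A by 1.42, 1.14 and 1.07.

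The genes with the largest falls changed less. AMOT, which encodes angiomotin, fell 2.36-fold (log2 -1.24, SE 0.17), INSIG1, a sterol-regulated protein of the endoplasmic reticulum, fell 2.0-fold (SE 0.19 on the log2 scale, limma adjusted p = 0.049), and MSMO1, an enzyme of cholesterol synthesis, fell 1.93-fold (log2 -0.95, SE 0.07, limma adjusted p = 0.000323). SHISA2, FLRT3 and TXNIP fell by 0.89, 0.88 and 0.71 on the log2 scale. CCDC138 fell by 0.74, but its other probe set went the opposite way. SHISA2 and TXNIP did not pass the test without wild type replicate 2 (adjusted p = 0.0503 and 0.0513). Without overexpression replicate 3 the calls of SYTL5, GEM, PPP1R15A, AMOT and CCDC138 ended (adjusted p = 0.0675, 0.0826, 0.0988, 0.0666 and 0.101). The call of SYTL5 also ended without wild type replicate 2, that of GEM without wild type replicate 3, and those of AMOT and CCDC138 without either of these. PPP1R15A and INSIG1 each kept their call in only 2 of the 6 fits that left out 1 array, those without wild type replicate 1 or overexpression replicate 2, and INSIG1 had adjusted p as high as 0.205 without wild type replicate 3.

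Of the 27307 probe sets, 130 passed the test after overexpression, 87 higher and 43 lower, and 33 of the higher and 4 of the lower changed at least 2-fold. They named 62 genes higher and 23 lower. The groups did not overlap at 17.6% of the probe sets, where chance gives 10%. The count was 29 without wild type replicate 2, 50 without wild type replicate 3, 71 without overexpression replicate 1 and 25 without overexpression replicate 3. With the term for replicate 1 it was 1109, and all 130 were among them. Calls made from replicates 2 and 3 alone numbered 220, and 215 of these (97.7%) had the same sign in replicate 1, against 64.8% of all probe sets.

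Among the 30 gene lists tested, fixed before the data were examined, 8 passed the limma camera test after overexpression. Of the 18 measured immediate early genes 8 rose, or 14 rose and 2 fell adjusted over the list alone, with a median log2 fold change of 0.83 (adjusted p = 3.61e-15, and adjusted p = 0.0164 with an estimated correlation). IER2 rose by 1.02 (SE 0.09) and DUSP1 by 0.84 (SE 0.09), beside EGR1 and ATF3. With the term for replicate 1 the list had adjusted p = 0.0651 with an estimated correlation. Of 15 cholesterol synthesis genes 3 fell, MSMO1, SQLE and INSIG1, or 9 fell adjusted over the list alone, with a median of -0.42 (adjusted p = 6.71e-10, and adjusted p = 0.0123 with an estimated correlation). SQLE, squalene epoxidase, fell by 0.69 (SE 0.10), a call that ended without wild type replicate 2 or overexpression replicate 3 (adjusted p up to 0.0826). Of 20 genes of the unfolded protein and ATF4 stress list, 3 rose (ATF3, PPP1R15A and the amino acid transporter subunit SLC3A2, 0.99, SE 0.13) and DDIT4 fell by 0.38 (SE 0.07). Adjusted over the list alone 10 rose and 1 fell, with a median of 0.21 (adjusted p = 3.21e-06, and adjusted p = 0.0164 with an estimated correlation). Leaving out overexpression replicate 3 ended the call of SLC3A2 (adjusted p = 0.0675), and that of DDIT4 was lost whichever array was left out, with adjusted p up to 0.221 without wild type replicate 2.

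The other 5 lists passed only with the preset correlation. The hypoxia and glycolysis list had a median of 0.14 (adjusted p = 0.00817, but adjusted p = 0.0941 with an estimated correlation), and VEGFA was its only member of 21 past the threshold, 1 adjusted over the list alone, with a call lost in 5 of the 6 fits that left out 1 array (adjusted p up to 0.215 without wild type replicate 2). Of 21 p53 target genes, CDKN1A, the p21 cell cycle inhibitor, rose by 0.60 (SE 0.10) and GADD45A by 0.61 (SE 0.10), and adjusted over the list alone 2 rose and 1 fell. The p53 median was 0.12 (adjusted p = 0.0284, but adjusted p = 0.201 with an estimated correlation). The call of CDKN1A was kept in 2 of the 6 fits that left out 1 array, and ended without wild type replicate 2, wild type replicate 3, overexpression replicate 1 or overexpression replicate 3 (adjusted p up to 0.132), and that of GADD45A whichever array was left out, with adjusted p up to 0.149 without wild type replicate 3. None of the 12 members of the MOF complexes list passed the limma test over all probe sets (4 at unadjusted p under 0.05, and 2 passed with the term for replicate 1), and 3 rose adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0169, but adjusted p = 0.227 with an estimated correlation). KAT8, the transfected gene itself, is a member of this list and among the 2 that passed with that term. The list was not tested without KAT8. The p53 and MOF complex lists each missed the threshold without wild type replicate 3, overexpression replicate 1 or overexpression replicate 3, with adjusted p up to 0.0613. No heat shock gene of 11 passed over all probe sets (3 at unadjusted p under 0.05, and 2 passed with the term for replicate 1) and 1 was lower adjusted over the list alone, with a median of -0.09 (adjusted p = 0.0284, but adjusted p = 0.201 with an estimated correlation). The heat shock list was lost without wild type replicate 2, wild type replicate 3, overexpression replicate 1 or overexpression replicate 3, with adjusted p up to 0.163. None of 18 ribosomal protein genes passed over all probe sets or adjusted over the list alone (0 at unadjusted p under 0.05), with a median of -0.09 (adjusted p = 0.00817, but adjusted p = 0.545 with an estimated correlation). The ribosomal list's direction turned under quantile normalization (adjusted p = 0.978), and its call was lost without wild type replicate 3 or overexpression replicate 3 (adjusted p up to 0.352).

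Knockdown against wild type asked what changed in cells given the small interfering RNA against MOF. Of 21 p53 targets 13 rose, of 21 HOX list genes 15, of 28 genes of G2/M and mitosis 10 and of 21 genes of hypoxia and glycolysis 11. These 4 lists passed the limma camera test (adjusted p = 3.65e-11, 6.15e-11, 4.68e-07 and 8.02e-06). The cell adhesion genes CDH1 and EPCAM fell, 2 of 4 measured genes of an epithelial marker list that did not pass camera (adjusted p = 0.213). The largest rise was that of KISS1R, the kisspeptin receptor, at 11.9-fold (log2 fold change 3.57, SE 0.20, n = 3 per group, limma adjusted p = 3.16e-05). ISG15, an interferon-induced ubiquitin-like protein, rose 3.17-fold (log2 1.66, SE 0.18), the small GTPase gene RAC3 2.9-fold (log2 1.54, SE 0.17) and PRTG, protogenin, 2.72-fold (log2 1.44, SE 0.12). EME2, a subunit of a structure-specific DNA endonuclease, rose 2.69-fold (log2 1.43, SE 0.11), and FAM174C, KRI1 and SYNGR3 rose by 1.41, 1.33 and 1.31 on the log2 scale.

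After KAT8 itself, the largest falls among genes that met the signal rule for naming were those of URB1-AS1 (log2 -2.11, SE 0.14), SELENOP, a selenium transport protein (log2 -1.88, SE 0.20), and GLT8D2 (log2 -1.82, SE 0.17). CDH1, which encodes E-cadherin, fell 3.48-fold (log2 -1.80, SE 0.14, limma adjusted p = 0.000107). HLA-DPA1 fell by 1.77 (SE 0.14), EGR1 by 1.76 (SE 0.16) and TMT1B by 1.70 (SE 0.15). All 16 of these genes, KAT8 included, passed the test in each of the 6 fits that left out 1 array.

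After knockdown 4289 probe sets passed the test (15.7% of those tested), 1861 higher and 2428 lower, naming 1134 genes higher and 1793 lower. Of these probe sets 270 rose and 330 fell at least 2-fold. The groups did not overlap at 35.2% of the probe sets, where chance gives 10%. The count was 2213 without wild type replicate 2, 2758 without wild type replicate 3, 2419 without knockdown replicate 2 and 2273 without knockdown replicate 3. It was 7637 with the replicate number as a block and 7706 with the term for replicate 1, and all 4289 were among the 7706. Of 5216 calls made from replicates 2 and 3 alone, 94.8% had the same sign in replicate 1, against 73.6% of all probe sets.

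Of the 30 lists 8 passed the camera test after knockdown. Of 21 p53 target genes 13 rose and none fell, or 18 rose adjusted over the list alone, with a median log2 fold change of 0.61 (adjusted p = 3.65e-11, and adjusted p = 0.0122 with an estimated correlation). GADD45A rose by 0.88 (SE 0.10), the sestrin gene SESN1 by 0.84 (SE 0.10), DDB2, a DNA damage recognition factor, by 0.92 (SE 0.13) and the death receptor gene TNFRSF10B by 0.66 (SE 0.09). Of 21 genes of the HOX list, which sets positional identity in the embryo and also holds MEIS1 and MEIS2, 15 rose and none fell, or 16 rose adjusted over the list alone, with a median of 0.62 (adjusted p = 6.15e-11, and adjusted p = 0.0131 with an estimated correlation). HOXB4 rose by 0.96 (SE 0.12), HOXB7 by 0.76 (SE 0.08), HOXC10 by 0.72 (SE 0.11) and HOXB2 by 0.61 (SE 0.08). Of 28 genes of G2/M and mitosis 10 rose and none fell, or 15 rose adjusted over the list alone, with a median of 0.28 (adjusted p = 4.68e-07, and adjusted p = 0.0126 with an estimated correlation). Among them CDC20 rose by 0.68 (SE 0.11), UBE2C by 0.41 (SE 0.06) and the mitotic kinase gene AURKA by 0.38 (SE 0.07). Of 21 hypoxia and glycolysis genes 11 rose and BNIP3L fell, by 0.52 (SE 0.10), or 15 rose and 1 fell adjusted over the list alone, with a median of 0.36 (adjusted p = 8.02e-06, and adjusted p = 0.0131 with an estimated correlation). P4HA1, a collagen hydroxylase, rose by 0.53 (SE 0.08) and KDM3A by 0.59 (SE 0.12).

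The remaining 4 lists passed with the preset correlation only. Of 14 interferon response genes 6 rose, or 6 rose and 2 fell adjusted over the list alone, with a median of 0.55 (adjusted p = 0.00371, but adjusted p = 0.128 with an estimated correlation). IFIT3 rose by 2.68 (SE 0.29), IFIT1 by 0.88 (SE 0.13) and IRF9 by 0.96 (SE 0.17), while HERC6 fell by 0.91 (SE 0.20). Of 18 immediate early genes 9 rose and EGR1 and MYC fell, or 10 rose and 2 fell adjusted over the list alone, with a median of 0.57 (adjusted p = 0.000114, but adjusted p = 0.135 with an estimated correlation). IER3 rose by 0.77 (SE 0.10) and IER2 by 0.66 (SE 0.09), and MYC fell by 0.68 (SE 0.10). Of 11 heat shock genes 4 rose, or 6 adjusted over the list alone, with a median of 0.22 (adjusted p = 0.00371, but adjusted p = 0.105 with an estimated correlation), and DNAJB1 rose by 0.54 (SE 0.08). None of 18 ribosomal protein genes passed over all probe sets or adjusted over the list alone (7 at unadjusted p under 0.05), with a median of -0.14 (adjusted p = 0.0184, but adjusted p = 0.608 with an estimated correlation and 0.052 with the replicate block). The ribosomal list also missed the threshold without wild type replicate 2, wild type replicate 3 or knockdown replicate 3 (adjusted p up to 0.224).

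The lists of DNA damage signalling and repair genes did not pass the test in either comparison with wild type, though single members changed after knockdown. Of 26 DNA damage signalling genes, PPM1D rose by 0.32 (SE 0.07) and CHEK2, a checkpoint kinase gene, fell by 0.35 (SE 0.10) after knockdown, or 3 rose and 2 fell adjusted over the list alone, with a median of 0.00 (adjusted p = 0.573). The CHEK2 call was lost in 5 of the 6 fits without 1 array (adjusted p up to 0.122 without knockdown replicate 2), and that of PPM1D without wild type replicate 2 (adjusted p = 0.0528) or knockdown replicate 1. Of 21 homologous recombination genes, PALB2, a partner of the recombination machinery, fell by 0.68 (SE 0.10) and RPA3 fell by 0.34 (SE 0.07), 2 also adjusted over the list alone (list adjusted p = 0.74). Of 16 nucleotide excision repair genes DDB2 rose while CETN2, ERCC4 and ERCC8 fell, by 0.60 (SE 0.07), 0.57 (SE 0.10) and 0.69 (SE 0.16), or 2 rose and 3 fell adjusted over the list alone (list adjusted p = 0.735). ERCC8 lost its call without knockdown replicate 2 or knockdown replicate 3 (adjusted p up to 0.0548). No member of the non-homologous end joining, Fanconi anaemia, mismatch repair or base excision repair lists passed after knockdown, over all probe sets or adjusted over the list alone (list adjusted p = 0.814, 0.963, 0.89 and 0.963), with 2, 5, 0 and 4 members at unadjusted p under 0.05. Over these 7 lists, 106 genes were measured, and after knockdown 2 rose, 6 fell and 98 did not pass, and 98 had a log2 fold change of less than 0.5 in size. The calls were 7.55% of the 106, against 15.7% of all probe sets tested, which include unnamed ones and several of the same gene. On the mean of each gene's probe sets 2825 of 12036 genes passed after knockdown, a larger share than 15.7%. After overexpression 0 of the 106 passed the limma test, 17 had unadjusted p under 0.05, and all had a log2 fold change of less than 0.5 in size. Only 0.476% of all probe sets passed there, so a count of 0 among 106 genes says little. With the term for replicate 1, 2 were higher and 6 lower after overexpression, and 10 higher and 14 lower after knockdown. With that term 4.06% and 28.2% of all probe sets passed in these comparisons, and the share over gene means was not computed with it. After overexpression, without that term, the 7 lists had adjusted p of 0.764 for DNA damage signalling, 0.456 for homologous recombination, 0.456 for non-homologous end joining, 0.97 for Fanconi anaemia, 0.26 for mismatch repair, 0.97 for nucleotide excision repair and 0.452 for base excision repair. Some genes of these lists, which the probe table used here does not pair with a probe set, were not analysed here.

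**Figure D2:**
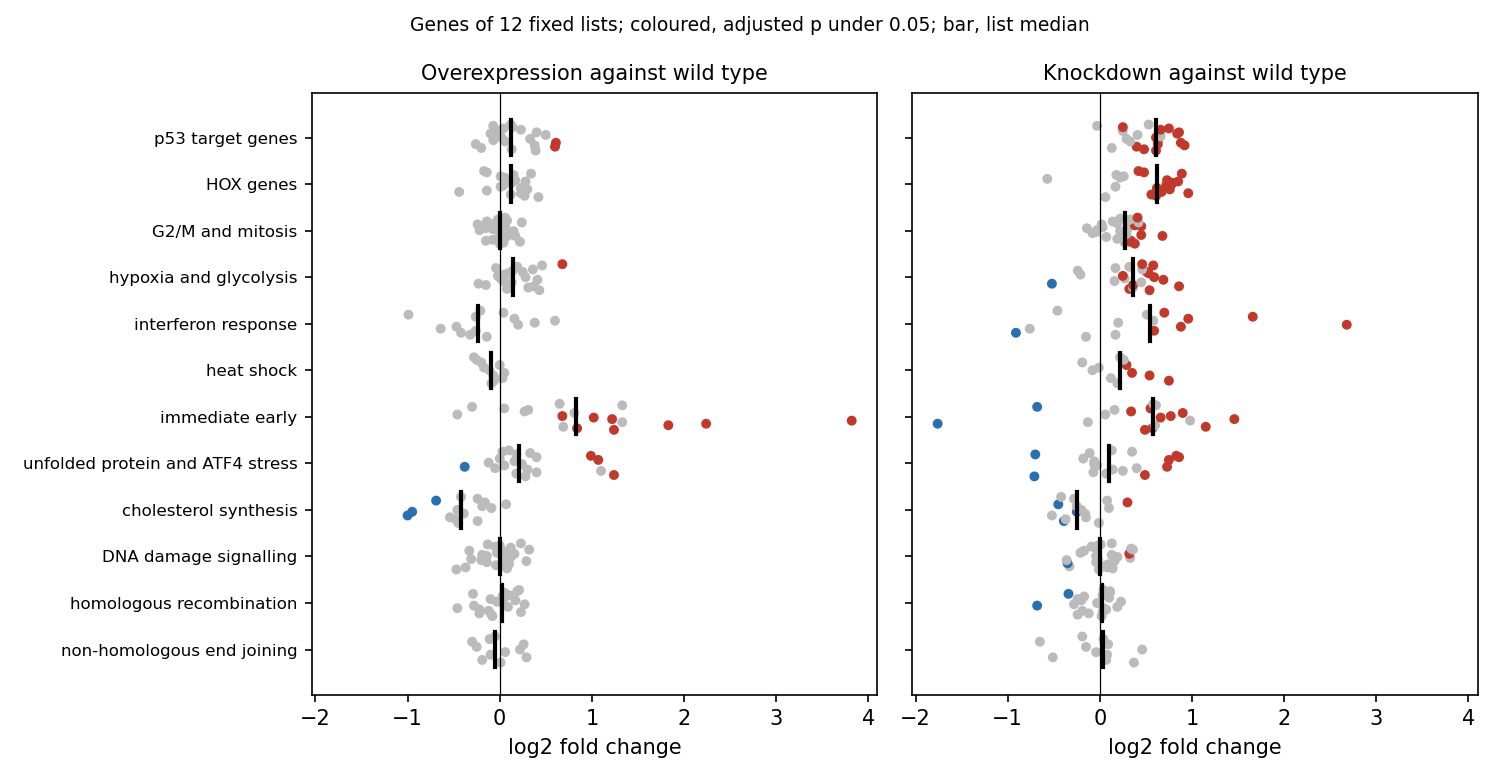
Log2 fold change of each measured gene of 12 of the gene lists after overexpression (left) and knockdown (right), both against wild type. Each point is a gene, coloured red where it rose and blue where it fell with limma adjusted p under 0.05, and black bars are list medians. The p53 targets had a median of 0.61 after knockdown and 0.12 after overexpression, the immediate early genes 0.57 and 0.83, and the DNA damage signalling genes 0.00 in both.

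Knockdown against overexpression compared the treated groups with each other, so that both groups had been transfected. The transfections were not matched, with small interfering RNA in knockdown and a plasmid in overexpression. EGR1 was 15.9-fold lower after knockdown than after overexpression (log2 fold change -4.00, SE 0.16, n = 3 per group, limma adjusted p = 9.16e-07), and KAT8 8.67-fold lower (log2 -3.12, SE 0.17, limma adjusted p = 9.2e-06). HLA-DPA1 was lower by 1.95 on the log2 scale (log2 -1.95, SE 0.14), MAFF at -1.91 (SE 0.12), ZCCHC12 at -1.88 (SE 0.13), GLT8D2 at -1.81 (SE 0.17), AMIGO2 at -1.75 (SE 0.25) and URB1-AS1 at -1.73 (SE 0.14). Higher after knockdown were KISS1R, 6.11-fold (log2 2.61, SE 0.20), FLRT3, 4.23-fold (log2 2.08, SE 0.11), ISG15, 3.79-fold (log2 1.92, SE 0.18), and SHISA2, 3.58-fold (log2 1.84, SE 0.11). PRTG, NAPEPLD and the axon guidance receptor gene ROBO2 were higher by 1.53, 1.42 and 1.39.

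In this comparison 3963 probe sets passed the test, 1571 higher and 2392 lower after knockdown, and 157 of the higher and 382 of the lower differed at least 2-fold. The groups did not overlap at 33.7% of the probe sets, where chance gives 10%. The count was 2040 without overexpression replicate 3, 2246 without knockdown replicate 2 and 2154 without knockdown replicate 3. It was 7334 with the replicate block and 7425 with the term for replicate 1, and all 3963 were among the 7425. Of 4909 calls made from replicates 2 and 3 alone, 95% had the same sign in replicate 1, against 71.8% of all probe sets.

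Of the 30 lists 7 passed between the treated groups, and each was higher after knockdown. Among lists that did not pass, the immediate early list had 1 gene higher and 7 lower (median -0.21, adjusted p = 0.247). The unfolded protein and ATF4 stress list also had 1 higher and 7 lower (median -0.17, adjusted p = 0.205). Of 21 HOX list genes 12 were higher, 16 adjusted over the list alone, with a median of 0.55 (adjusted p = 8.03e-09, and adjusted p = 0.026 with an estimated correlation), among them HOXB5 at 1.11 (SE 0.13) and MEIS2 at 0.60 (SE 0.07). Of 21 p53 targets 10 were higher, 14 adjusted over the list alone, with a median of 0.35 (adjusted p = 2.74e-07, and adjusted p = 0.0211 with an estimated correlation), among them SESN1 at 0.94 (SE 0.10) and the death receptor gene FAS at 0.89 (SE 0.13). Of 28 genes of G2/M and mitosis 8 were higher, 10 adjusted over the list alone, with a median of 0.23 (adjusted p = 3.18e-07, and adjusted p = 0.0211 with an estimated correlation). Of 11 heat shock genes 6 were higher, 7 adjusted over the list alone, with a median of 0.29 (adjusted p = 1.39e-05, and adjusted p = 0.0262 with an estimated correlation), among them DNAJB1 at 0.61 (SE 0.08) and HSPH1 at 0.50 (SE 0.07). With the term for replicate 1 the heat shock list had adjusted p = 0.0605 with an estimated correlation. Of 14 interferon genes 7 were higher, 8 adjusted over the list alone with 1 lower, with a median of 0.57 (adjusted p = 0.000432, but adjusted p = 0.0762 with an estimated correlation). Of 21 hypoxia and glycolysis genes 3 were higher and 1 lower, 6 and 2 adjusted over the list alone, with a median of 0.21 (adjusted p = 0.0128, but adjusted p = 0.0816 with an estimated correlation). Of 15 cholesterol synthesis genes 4 were higher, MSMO1 and SQLE among them, and 1 lower, the same numbers adjusted over the list alone, with a median of 0.23 (adjusted p = 0.0152, but adjusted p = 0.0889 with an estimated correlation). The DNA damage signalling list had a median of 0.06 between the treated groups (adjusted p = 0.387), with 2 genes higher and 2 lower, over all probe sets and adjusted over the list alone. The other repair lists had adjusted p of 0.99 for homologous recombination, 0.449 for non-homologous end joining, 0.91 for Fanconi anaemia, 0.404 for mismatch repair, 0.713 for nucleotide excision repair and 0.596 for base excision repair. Over the 106 genes of the 7 lists, 6 were higher and 8 lower after knockdown than after overexpression, or 15 and 15 with the term for replicate 1. The calls without that term were 13.2% of the 106, against 14.5% of all probe sets, and with it 27.2% of all probe sets passed. On the mean of each gene's probe sets, without that term, 2747 of 12036 genes passed, a larger share than 14.5%. In nucleotide excision repair 2 were higher and 4 lower, or 2 and 5 adjusted over the list alone, among them RAD23B at 0.42 (SE 0.09) and CETN2 at -0.46 (SE 0.07). In the Fanconi anaemia list FANCE was higher (0.51, SE 0.11) and the nuclease gene FAN1 lower (-0.55, SE 0.10), or 2 and 1 adjusted over the list alone. In homologous recombination EXO1 was higher (0.29, SE 0.07) and PALB2 lower (-0.41, SE 0.10), 1 and 1 also adjusted over the list alone, calls lost in 5 and 4 of the 6 fits without 1 array (adjusted p up to 0.0958 and 0.076, both without overexpression replicate 3). No member of the mismatch repair, base excision repair or non-homologous end joining lists passed the limma test, over all probe sets or adjusted over the list alone, with 1, 4 and 4 members at unadjusted p under 0.05.

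The probe sets called after overexpression were also compared with those called after knockdown. Both comparisons share the wild type arrays, so the numbers for independent lists are not those expected without a shared response. No such numbers were simulated for calls. Of the 87 that rose after overexpression 53 also rose after knockdown, where independent lists would share 5.93, and 5 fell, where independent lists would share 7.74. Of the 43 that fell, 8 also fell (3.82 for independent lists) and 8 rose (2.93). With the term for replicate 1, 329 rose in both, where independent lists would share 79.8, and 211 fell in both (75.7). With that term 31 rose after overexpression and fell after knockdown (91.5), and 46 fell after overexpression and rose after knockdown (66), so here the latter lay below the number for independent lists. By gene, 44 were called in both comparisons, 36 in the same direction. GADD45B rose by 1.23 (SE 0.14) after overexpression and by 1.20 (SE 0.14) after knockdown, CCN1 by 1.65 and 0.56, and ID1 by 0.80 and 0.71. The 8 genes called in opposite directions were EGR1, ZCCHC12, BEX1 and C11orf96, which rose after overexpression and fell after knockdown, and FLRT3, SHISA2, DDIT4 and IVNS1ABP, which fell and rose. GADD45B, ID1, BEX1, C11orf96 and IVNS1ABP were chosen after their values were seen.

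Both comparisons used the same 3 wild type arrays, whose chance values enter both fold changes. Across the 27307 probe sets the fold changes had Pearson r = 0.371, and 100 simulations of unchanged groups against shared controls gave a mean of 0.501. The covariance was 0.044, against 0.0232 in the simulations, a difference of 0.0208. The difference of the replicate 1 arrays adds to the residual variances behind these simulations, although it cancels between groups that hold 1 such array each. With the residual variances of the fit with the term for replicate 1, a choice made after seeing the data, 100 simulations gave a mean r of 0.5 and a mean covariance of 0.0176, a difference of 0.0265. The share of all probe sets with the same sign in both comparisons was 61.8%, against a mean of 66.7% (66 to 67.3) in the first 100 simulations of unchanged groups. For unchanged groups of equal size that share a control, r near 0.5 and such a share follow from the sharing alone, whatever the variances. Real changes in either group move both values, so neither shows less agreement than chance or decides how much the shared arrays contributed. Genes are not independent replicates, so no p is given, and with 3 wild type arrays the controls could not be split into parts of at least 2, so part of the overlap may come from the shared controls.

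**Figure D3:**
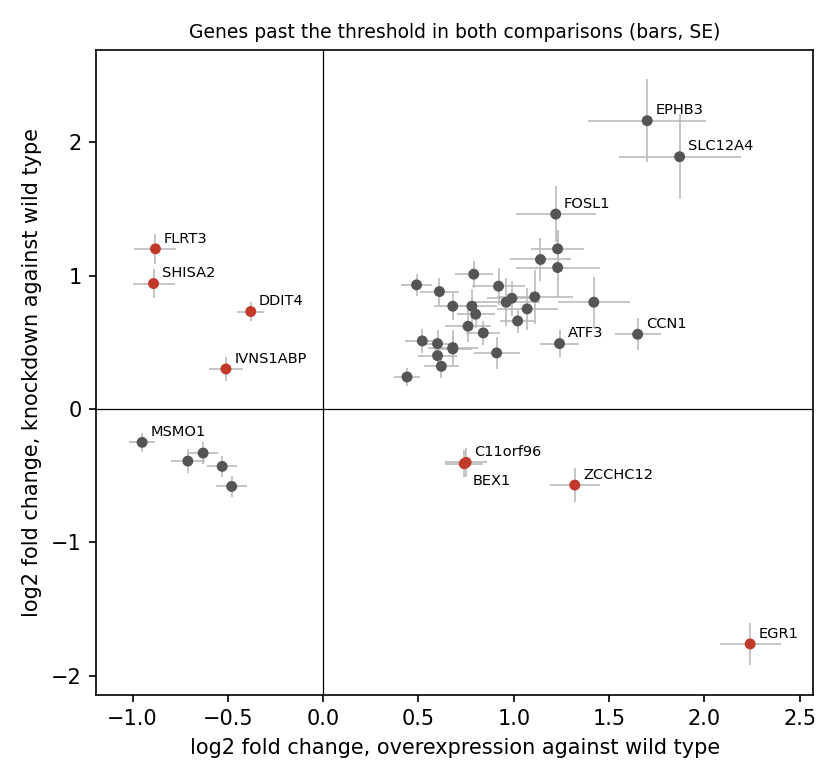
Log2 fold change after knockdown against log2 fold change after overexpression, both against wild type, for the 44 genes called in both comparisons. Bars are standard errors, grey points are the 36 genes with the same direction and red points the 8 with opposite directions, with EGR1 at 2.24 and -1.76.

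As a sign of RNA quality, the log2 ratio of 3′ to 5′ control probe sets was compared between groups. Averaged over GAPDH and ACTB it was 0.257 ± 0.0249 (SD, n = 3) in wild type, 0.205 ± 0.0508 (SD, n = 3) after overexpression and 0.193 ± 0.0363 (SD, n = 3) after knockdown. Exact two-sided permutation tests against wild type gave p = 0.2 and p = 0.1, where 0.1 is the smallest possible. For ACTB alone the ratio differed from wild type by -0.148 after overexpression and -0.174 after knockdown, and for GAPDH by 0.0447 and 0.0464. The same permutation tests gave p = 0.1 for ACTB and p = 0.5 for GAPDH in both comparisons. All ACTB ratios of both treated groups lay below those of wild type. Among markers of other cell types, the keratin-rich epithelial list had 2 of 4 measured genes lower after knockdown, CDH1 and EPCAM (-1.75, SE 0.23), 2 also adjusted over the list alone, with a median of -0.90 (adjusted p = 0.213). With the term for replicate 1, 2 of the 4 were lower and 1 higher. The fibroblast and neuronal lists had adjusted p = 0.953 and 0.963 after knockdown, and the 3 lists had 0.371 (fibroblast), 0.515 (neuronal) and 0.97 (epithelial) after overexpression. After knockdown 1 of 9 neuronal genes was lower, GAP43 (3 adjusted over the list alone), in all 6 fits that left out 1 array. Of 5 fibroblast genes COL3A1 was lower, a call kept in 1 of the 6 fits. Between the treated groups 2 epithelial and 2 neuronal genes were lower, and 1 fibroblast gene was higher and 1 lower (list adjusted p = 0.222, 0.713 and 0.438).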

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

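Of the choices below, the fit of replicates 2 and 3 alone was chosen after seeing the data. Where counts moved, the cause was not tested unless said. After overexpression 130 probe sets passed. The count was 1022 with the replicate block, 1109 with the term for replicate 1, 70 without the variance trend, 3004 with array weights, 220 from replicates 2 and 3, 27 with only the 2 groups compared (fewer samples) and 37 at 2-fold (a stricter threshold). Leaving out 1 array in turn gave 25 (without overexpression replicate 3) to 97, with 29, 50 and 71 without wild type replicate 2, wild type replicate 3 and overexpression replicate 1. After knockdown 4289 passed, against 7637 with the block, 7706 with the term, 7196 with array weights, 600 at 2-fold and 2825 over gene means (fewer tests). Leave-one-out gave 2213 to 3653, with 2213, 2758, 2419 and 2273 without wild type replicates 2 and 3 and knockdown replicates 2 and 3. Between knockdown and overexpression 3963 passed, against 7334 with the block, 7425 with the term, 8813 with array weights and 539 at 2-fold. Leave-one-out gave 2040 to 3289, with 2040, 2246 and 2154 without overexpression replicate 3, knockdown replicate 2 and knockdown replicate 3.

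KAT8 kept its direction and its side of the threshold in both knockdown comparisons under every alternative run, with leave-one-out ranges of -2.80 to -2.45 against wild type and -3.31 to -2.96 against overexpression. Its log2 fold change of 0.51 after overexpression passed with the replicate block (0.51, adjusted p = 0.0381) and with the term for replicate 1 (0.51, adjusted p = 0.0478), and under no other alternative, with a leave-one-out range of 0.42 to 0.61 and adjusted p of 0.314 to 0.526. Camera with an estimated correlation called 3, 4 and 4 lists in place of 8, 8 and 7, for overexpression and knockdown against wild type and for knockdown against overexpression. Fry, which does not compare a list with other genes, called 13 and 14 in the comparisons with knockdown, and the filter at the 75th percentile 4 between the treated groups. Leave-one-out gave 4 to 8, 7 to 8 and 7 lists, with 4 without wild type replicate 3 or overexpression replicate 3 and 5 without overexpression replicate 1 after overexpression. The ribosomal list after overexpression turned under quantile normalization, with a median of -0.00. The replicate block ended the call of the ribosomal list after knockdown (adjusted p = 0.052) and, KAT8 after overexpression and the counts apart, it changed no other call in the comparisons with knockdown.

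The correlation of the fold changes, 0.371, was 0.481 with no filter, 0.301 with the filter at the 75th percentile, and 0.333 to 0.467 leaving out 1 array, with 0.467 and 0.427 without wild type replicates 1 and 3. The 3′ to 5′ difference from wild type was 0.0447 for GAPDH and -0.148 for ACTB after overexpression, and 0.0464 and -0.174 after knockdown. Of 3419 values of 203 named gene results that passed, 3079 kept direction and call, 340 lost the call and 0 reversed. For 23 lists that passed, 397 of 437 values were kept, 39 lost and 1 reversed, and for the 67 others 17 of 1264 values gained a call. Array intensities carry no counts, so the precision is limited by the number of arrays and by dim signals.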

Other observations

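Other fixed lists changed in part after knockdown. Of 12 genes of the MOF complexes list, OGT, a glycosyltransferase of the NSL complex, rose by 0.51 (SE 0.08), MSL1 rose by 0.59 (SE 0.11), with its other probe set going the opposite way, and KANSL2 rose by 0.29 (SE 0.08, a call lost in 5 of 6 fits without 1 array, with adjusted p up to 0.131 without wild type replicate 3), while KAT8 fell. That list did not pass the camera test (median 0.13, adjusted p = 0.205), with 3 higher and 1 lower also adjusted over the list alone. Of 23 autophagy genes 3 rose, SQSTM1 by 0.70 (SE 0.09), and 6 fell, among them WIPI1 by 0.96 (SE 0.16) and TFEB, a transcription factor of lysosomal genes, by 0.81 (SE 0.17), or 4 and 6 adjusted over the list alone (list adjusted p = 0.814). Of 20 genes of the unfolded protein and ATF4 stress list 5 rose, DDIT4 by 0.73 (SE 0.07), and 2 fell, asparagine synthetase ASNS by 0.71 (SE 0.08) and the cystine transporter gene SLC7A11 by 0.70 (SE 0.11), 5 and 2 also adjusted over the list alone (list adjusted p = 0.199). Of 21 oxidative phosphorylation genes CYC1 rose by 0.55 (SE 0.09) and 3 fell, NDUFV1 by 0.61 (SE 0.07) among them, or 1 and 6 adjusted over the list alone (list adjusted p = 0.252).

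Of 10 genes of RNA interference, DROSHA fell by 0.61 (SE 0.10) after knockdown, and 2 genes rose and 2 fell in all (list adjusted p = 0.59). The lists after knockdown with adjusted p above 0.05 and not named so far were other histone acetyltransferases (0.61), histone deacetylases (0.453, with HDAC8 lower by 0.59 on the log2 scale, log2 -0.59, SE 0.11), G1/S and DNA replication (0.573, with GINS1 at -0.51, SE 0.08), apoptosis (0.413), cholesterol synthesis (0.207), replication-dependent histones (0.573) and chromatin remodelling (0.448). After overexpression those not named so far were other histone acetyltransferases (0.516), histone deacetylases (0.97), G1/S and DNA replication (0.97), G2/M and mitosis (0.97), apoptosis (0.146, with PMAIP1 higher, 0.65, SE 0.08), interferon response (0.157), oxidative phosphorylation (0.26), autophagy (0.97), HOX (0.258), replication-dependent histones (0.428), chromatin remodelling (0.97) and RNA interference (0.442).

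All tests below were chosen after the results were seen, except the test of the shared wild type arrays. With 3 against 3 arrays there are 10 splits of 6 arrays, too few for a share under 0.05. The real split, 1 of the 10, gave 130, 4289 and 3963 probe sets in the 3 comparisons, in the order of the report, and the highest of the other splits gave 0 in each with limma. At unadjusted p under 0.05 the other splits gave up to 5331, 2227 and 2450, against 3351, 8370 and 7984 for the real ones. The 5331 came from a split that put both replicate 1 arrays of wild type and overexpression on the same side, with overexpression replicate 3, so it follows in part the difference of the replicate 1 arrays, and it exceeds the real count of 3351, for which the term for replicate 1 gave 5546.

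Most genes called in both comparisons with wild type moved the same way, although the labels give opposite treatments of MOF, of which only the fall of KAT8 passed the test (overexpression adjusted p = 0.259, or 0.0478 with the term for replicate 1). For the 36 genes called in the same direction, transfection and the change in MOF cannot be told apart, since no mock-transfected group is among the samples. The 8 genes called in opposite directions exclude nothing here, since they were picked by their direction and the transfections differed (a plasmid and small interfering RNA). Chance values of the shared wild type arrays were tested by taking calls from replicates 2 and 3 of overexpression and wild type to the replicate 1 arrays of knockdown and wild type, which share no array with them. There 66.8% of 220 calls had the same sign, against 53.9% of all probe sets. The 95% exact binomial interval was 60.2 to 73, which takes genes as independent and is therefore too narrow. Although this met the bound of 60 set beforehand, it rests on 1 pair of arrays. In the same test 6 of only 8 calls had the same sign with replicate 2 left out, and 1 of only 3 with replicate 3 left out. Both of those intervals reached below 60, so the shared arrays stay open as part of the cause.

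The rise of p53 targets after knockdown is a pattern that a biologist would follow up beside the DNA damage lists, which did not pass. Scaling of the arrays is argued against: the list median was at least 0.61 under quantile normalization and median centring, against a median of 0.009 over all probe sets. Coverage of transcript 5′ ends, read by the ACTB controls, would in proportion to the ACTB shift give a list median of 0.52 after overexpression, above the 0.12 found (quartiles -0.04 to 0.38). That goes against it only if list shifts are proportional to the ACTB shift and overexpression itself leaves the list unmoved, neither of which was tested. The GAPDH ratio moved the other way, by 0.0447 after overexpression and 0.0464 after knockdown. With the ACTB shift less 1 standard error the proportional value is 0.28, within those quartiles, so this explanation stays open. The list also passed camera after overexpression with the preset correlation (adjusted p = 0.0284), but not with an estimated one (adjusted p = 0.201). CDKN1A rose by 0.60 after overexpression and 0.40 after knockdown, and GADD45A by 0.61 and 0.88. Between the treated groups the list was higher after knockdown, with a median of 0.35 (camera adjusted p = 0.0211 with an estimated correlation), but their transfections differed. Loss of MOF, transfection and the interfering RNA itself are confounded in the knockdown group, so a p53 response to low MOF is a hypothesis that these arrays may fit but cannot single out.

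The replicate 1 arrays stood apart from replicates 2 and 3 in every group. A processing batch is a candidate explanation that goes with the data: deviations from the group means correlated at 0.35 or more between replicate 1 arrays of different groups, and between -0.38 and -0.13 for replicate 1 against other numbers, and the added poly-A controls were 2.23-fold dimmer there. Deviations from a group mean cancel within the group, so the negative correlations follow on average from the positive ones and are no separate evidence. No biological explanation was tested, because the labels give none for the numbers.

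The 18S ribosomal RNA 5′ control probe set ranged from 4036.2 in overexpression replicate 1 to 101559 in wild type replicate 3, with 9416.5 and 32342.5 in the other wild type arrays.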
